A study of Drosophila melanogaster with 3 samples.

How the data were processed

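3 ChIP-seq libraries of a transgenic *Drosophila* line expressing zen fused to GFP were analysed, each a separate biological replicate per the labels. Whole embryos of mixed sex aged 0 to 4 h were used, chromatin was fragmented by sonication to 200 to 800 bp, and the immunoprecipitation used an antibody against GFP, per the labels. All 3 libraries belong to a single group, and no library of another condition was analysed here.

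The authors called peaks on the dm6 genome for each library and for the pooled libraries against the same control alignments, and deposited a set thresholded by the irreproducible discovery rate (IDR), per the file notes deposited with the samples. The peak caller, the aligner and their versions are not given in the sources used here. Each list is in narrowPeak format, with an interval, a summit, a signal value and a q-value per peak. The deposited signal value is a score from the authors' caller, computed against the control. Its scale differs between lists, so it was used only to rank peaks within a list. The −log10 q-value that the authors deposited for each peak was not used in a test. Each library list and the pooled list held 30000 summits, and the IDR set of 7405 was exactly the top 7405 of the pooled list by signal. Some intervals were listed once per summit: the IDR set had 7405 summits in 7243 intervals, of which 148 held several summits. No peak was identical in both coordinates and signal value between libraries. The lists give no read counts, so the depth per library is unknown, and no counting interval can be given. Median interval width was 430 bp in replicates 1 and 2 and 360 bp in replicate 3.

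Analyses were limited to arms 2L, 2R, 3L, 3R, 4 and X. For comparisons across replicates, the top 7405 summits of each library by signal were used, and a summit was shared when another lay within 100 bp. Chance overlap came from 1000 circular shifts of a library along each arm. Placement used the Ensembl annotation of release 115, with classes taken in the order coding sequence, 5' UTR, 3' UTR, other exon, intron and intergenic, and 10000 circular shifts along each arm as a two-sided permutation test. Arm densities were given without a test.

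A gene was called bound when an IDR summit lay in the gene body extended by 2000 bp on either side. For each of 19 lists, the number of bound genes was compared with 100000 random lists of protein-coding genes matched gene by gene on the decile of territory length, two-sided, with Benjamini-Hochberg adjustment over lists. The lists covered amnioserosa and dorsal ectoderm, Dpp pathway, neurogenic ectoderm, mesoderm, gap and head, pair-rule, segment polarity, Hox, cellularization, germ plasm, hemocyte, muscle structure, vision, heat shock, antimicrobial peptide, ribosomal protein, proteasome, odorant and gustatory receptor and cuticle protein genes. They were written from textbook knowledge or symbol patterns. Of the symbols, *nos* was not matched to the annotation, and *h* was matched as *hry*. The dorsal and mesoderm lists were compared by Fisher's exact test.

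Motifs were counted on either strand within 100 bp of the summit and in a window of the same width centred 1000 bp away on a randomly chosen side. Discordant pairs of windows were tested by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over 17 motifs. Log2 ratios of shares had 0.5 added to each count. TAAATT and CGAGTA served as controls with the bases of TAATTA and CAGGTA in another order. For motifs by signal, the 1481 strongest and the 1481 weakest IDR summits were compared by Fisher's exact test. The window around *zen* was ranked among other windows of 100 kb that do not overlap it.

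Lists, motifs, windows, tests and most other settings were fixed before the data were examined. The genes named in the text were set by a rule written at the same time: the 10 strongest IDR peaks with their overlapping or nearest gene, every gene of the dorsal list, the pair of genes with the strongest summits in each other list, *zen*, and the 5 territories with the most summits. A gene that this rule names is not reported here. Unbound members of lists, *bcd*, *Cpr* and genes of broad intervals were named after their values were seen. The other settings fixed then were the 3702 strongest IDR peaks, the 14810 strongest pooled peaks, the consensus of a pair of libraries without the remaining replicate, other match distances and overlaps, all 30000 peaks per library, start-site distances of 200 and 1000 bp, territories of 5000 bp or within 1000 bp of a start, a background of genes with a known symbol, motif windows of 50 bp, flanks at 3000 bp, windows matched on GC content in bins of 5 percentage points, and windows of 50 and 20 kb around *zen*. Shifts of 5 to 50 kb per summit, GC bins for motifs by signal (with 10000 permutations within bins), and the strongest summit of each interval were added after the data were seen.

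The placement and motif steps were tested on 7405 random summits. The list step was tested with drawn gene lists on the real IDR set and 13945 protein-coding genes. Fewer shifts and random lists were used than in the analysis. Of 20 random peak sets, 1 gave a placement p below 0.05, and a set with planted summits near start sites gave 38.8% against 39.5% expected. Of 200 random gene lists, 5 gave a p below 0.05. All 200 lists drawn only from bound genes did, an outcome that such lists nearly fix in advance. A planted motif gave a difference of 9.32 percentage points and an unplanted motif an adjusted p of 0.245. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 with a random seed of 1.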

Results

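Chromatin immunoprecipitation and sequencing was carried out on a transgenic *Drosophila melanogaster* line that expresses Zen, a homeodomain protein of the early embryo, with GFP fused to its C terminus. The immunoprecipitation used an antibody against GFP on mixed-sex whole embryos aged 0 to 4 h, in 3 biological replicates that form a single group. Each library had its own list of 30000 peak summits on the dm6 genome. A list of 30000 summits came from the pooled libraries, and an IDR set (peaks kept by the irreproducible discovery rate) held 7405 summits in 7243 intervals. The lists carry no read counts, so the depth of each library is unknown. The design holds no second condition, and the comparisons were therefore between binding positions and chance, between gene lists and between replicates.

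Dorsal genes with summits were sought in a list of 16 genes. They belong to the amnioserosa, the extraembryonic tissue that needs *zen*, and to the dorsal ectoderm. No library without the tagged protein was analysed here. Zen binding at a gene was therefore not separated from open chromatin recovered regardless of the tagged protein, in this list or the others. All 16 genes had at least 1 IDR summit in the gene body or the 2 kb on either side, and 69 summits fell in these territories. Random lists of genes matched on territory length held 9.33 such genes on average (two-sided permutation test, p = 0.00024, adjusted p = 0.00114 over 19 lists). The libraries' own strongest 7405 summits marked 16, 15 and 15 of the genes, a mean of 15.3 ± 0.577 (SD, n = 3). The median rank of the strongest summit per gene was 423.5 among the 7405 IDR summits, ordered by the signal value the authors gave each peak.

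The strongest summit of the dorsal list lay 1007 bp upstream of *egr*, which encodes the fly tumor necrosis factor, in an intergenic interval on arm 2R from 10076869 to 10078573 (rank 7). *ush*, a zinc-finger cofactor of GATA factors, held 14 summits, the strongest in an intron on 2L from 480886 to 481303 (rank 16). *pnr*, a GATA factor of the dorsal ectoderm, held 6 summits, with the strongest in an intron on 3R from 16028514 to 16029332 (rank 36). The peptidase gene *Ance* followed at rank 103, with a summit 1105 bp upstream of its start in an annotated 5' UTR. *cv-2*, which encodes a secreted BMP-binding protein, had 8 summits and an intronic summit at rank 168. The T-box genes *Doc1*, *Doc2* and *Doc3* held 5, 9 and 1 summits, with strongest ranks of 1373, 179 and 705. The strongest *Doc2* summit had no counterpart within 100 bp in the list of replicate 3. The homeobox gene *C15* ranked at 208 with 2 summits, and the LIM-homeodomain gene *tup* at 544 with 3. The BMP ligand gene *dpp* had 8 summits, the strongest in an intron at rank 939, and the protease gene *tld* had 1 summit, 369 bp upstream of its start, at rank 678. The weakest members, each with a single summit, were the zinc-finger gene *peb* (rank 3351), the homeobox gene *mirr* (rank 5085) and *zen2*, the paralog of *zen* (rank 6257). The *peb* summit had no counterpart in the lists of replicates 1 and 3.

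**Figure D1:**
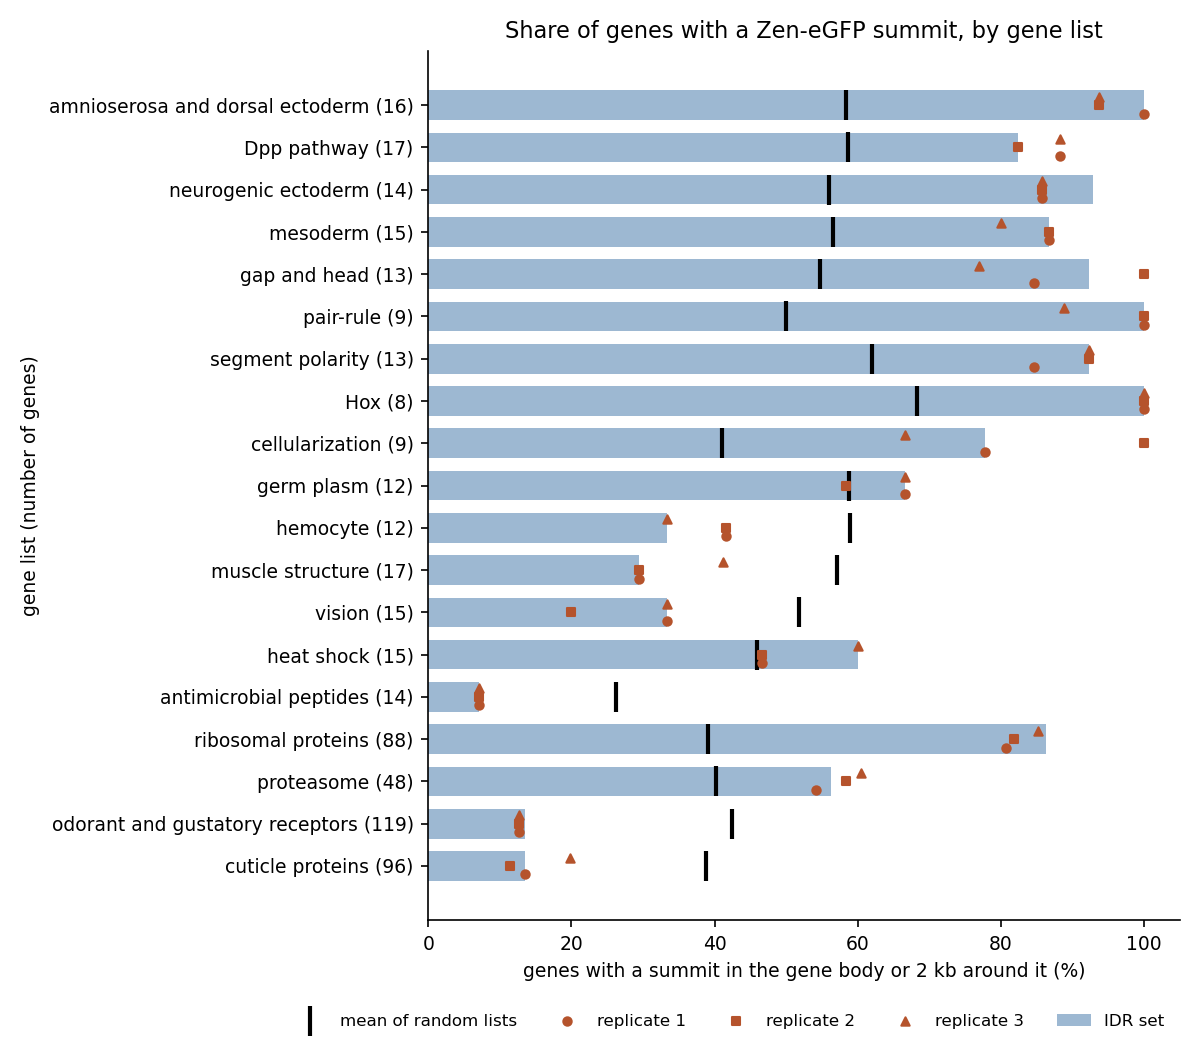
Share of genes with a summit in the gene body or the 2 kb on either side (x axis, percent) for 19 gene lists (y axis, number of genes in brackets). Bars are the IDR set, symbols the strongest 7405 summits of each of the 3 replicates, and black ticks the mean of 100000 random lists matched on territory length; the amnioserosa and dorsal ectoderm list reached 16 of 16 genes against 9.33 expected.

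*zen* itself (3R, 6752864 to 6754194, minus strand) had 3 summits in its territory. The strongest of them lay 415 bp upstream of its start, in an intergenic interval from 6754196 to 6754936 (rank 303; ranks 256, 175 and 759 in replicates 1, 2 and 3). Farther upstream, 8967 bp from the *zen* start, lay the summit with the highest signal of the whole IDR set, in an interval of 1484 bp from 6762113 to 6763596. This summit fell in introns of *Ama*, a gene for a secreted immunoglobulin-domain protein, and of a noncoding RNA gene on the other strand, 243 bp from an annotated *Ama* start. It ranked 1, 1 and 7 in replicates 1, 2 and 3. A further summit, 5483 bp upstream of *zen* and next to *bcd*, the gene of the maternal anterior determinant, ranked 229. In the 100 kb centred on *zen*, 16 IDR summits were found, against a median of 5 in 1334 other windows, which placed the window at the 95.5th percentile. The same window was at the 98.2nd, 97.4th and 98.6th percentile in replicates 1, 2 and 3. A transgene that carries *zen* can add copies of this region, and the peak lists do not tell the copies apart.

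**Figure D2:**
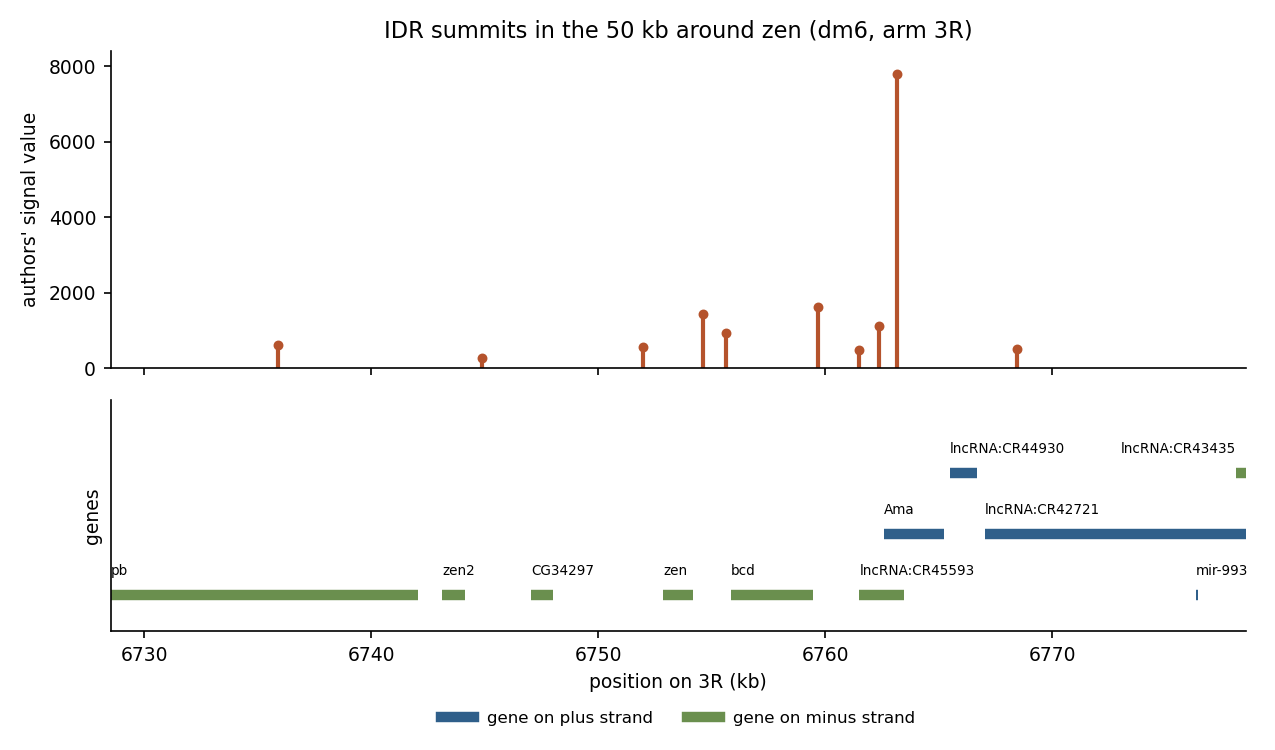
IDR summits in the 50 kb centred on *zen* (x axis, position on arm 3R in kb, dm6), with the authors' signal value of each summit in the upper panel (y axis, no unit) and annotated genes in the lower panel, colored by strand. The tallest line is the summit at 6763161 in the *Ama* intron, with a signal of 7785; the summit next to the *zen* start has a signal of 1442.

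Beyond this locus, the 10 strongest IDR peaks included sites at genes of several kinds. Those at ranks 2 to 5 lay within 474 bp of a start site: in an intron of *px* (2R, 22514090 to 22514517), next to *Art3* (3R, 15229319 to 15229741), next to *CG14100* (3L, 19590421 to 19590823) and in an intron of *ph-p*, a Polycomb group gene (X, 2137130 to 2137589). These 4 peaks ranked 1, 2, 3 and 4 in replicate 3. The peak at rank 6 lay in an intron of *bbg* (3L, 14452424 to 14453311) and ranked 2, 2 and 78 in replicates 1, 2 and 3, and the *egr* peak ranked 3, 3 and 97. The remaining 3 lay outside annotated genes. Those near *CG13921* (3L, 1746570 to 1746988) and *CHMP2B* (3L, 5139314 to 5139692) were also close to a start site, at 121 and 106 bp. The peak near *CycB* (2R, 22802626 to 22803240) lay 3342 bp from the nearest start. The territories with the most IDR summits belonged to *jing* (28), *CG42342* (25), the Hox gene *Antp* (21), *kirre* (20) and the homeobox gene *hth* (18). These counts were not scaled by length, and a long gene can hold more summits for that reason alone. *kirre*, for example, spans X from 2740384 to 3134532. Of 13945 protein-coding genes, 6533 (46.8%) had a summit in their territory, and the libraries gave 46.2 ± 1.90% (SD, n = 3).

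Other genes that pattern the embryo were bound in large part too. All 9 pair-rule genes carried a summit, against 4.50 in matched random lists (two-sided permutation test, adjusted p = 0.0122), led by *ftz* (rank 53, 311 bp upstream of its start) and *opa* (rank 117, intron). The neurogenic ectoderm list had 13 of 14 genes bound against 7.85 (permutation, adjusted p = 0.0172), with *Dr* (rank 524) and the FGF gene *ths* (rank 616) strongest and *sc* unbound. The gap and head list had 12 of 13 against 7.12 (permutation, adjusted p = 0.0233), led by *ems* (rank 480) and *cnc* (rank 530), with *btd* unbound. Genes per library were 8.67 ± 0.577 for the pair-rule list, 12 in each library for the neurogenic list and 11.3 ± 1.53 for the gap and head list (SD, n = 3). These lists passed under fewer settings than the dorsal list, whose adjusted permutation p was 0.000633 to 0.0482 under the other settings run. The lists differ in size, so this does not rank their excess over chance. Within 1 kb of a start, 12 of 16 dorsal genes were bound against 5.83 (permutation, adjusted p = 0.00811). There the pair-rule list had 9 of 9 against 3.10 (0.000456). The dorsal list had 14 of 16 in the 3702 strongest peaks and without replicate 1 or replicate 2. The neurogenic and gap and head lists did not pass without replicate 1 (permutation, adjusted p = 0.147 and 0.0678) or without replicate 2 (0.0718 and 0.0852). They did not pass in the 3702 strongest peaks (0.278 and 0.158) or against genes with a known symbol (0.0513 for both). Bound genes still outnumbered those of the random lists in each of these settings. In the 3702 strongest peaks they were 8 of 14 against 5.10 and 8 of 13 against 4.51. In the looser set of 14810 peaks the pair-rule and the gap and head lists did not pass (permutation, adjusted p = 0.106 and 0.0763). There 9 of 9 and 13 of 13 genes were bound, against 6.01 and 9.29. With territories of 5 kb the pair-rule list did not pass either (9 of 9 against 5.77, permutation, adjusted p = 0.0744). Every gene was bound in these cases, so a larger excess was not possible.

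Several further patterning lists lay above their random lists without passing the adjusted test. For the mesoderm list, 13 of 15 genes were bound against 8.47 expected (permutation, adjusted p = 0.0527), with *Mef2* (rank 66) and *zfh1* (rank 147) strongest and *Mes2* and *bap* unbound. The Dpp pathway list, which shares *dpp*, *tld* and *cv-2* with the dorsal list, had 14 of 17 against 9.97 (permutation, adjusted p = 0.0943). Its strongest members were *shn*, a zinc-finger effector of Dpp signaling with 16 summits (rank 138), and *cv-2*. Segment polarity genes had 12 of 13 against 8.06 (permutation, adjusted p = 0.0622), led by *nkd* (rank 292) and *lbe* (rank 432). All 8 Hox genes were bound against 5.46 (permutation, adjusted p = 0.128), led by *Scr* (rank 89) and *abd-A* (rank 129). Cellularization genes had 7 of 9 against 3.69 (permutation, adjusted p = 0.0693), led by *Z600* (rank 40) and *slam* (rank 386). In the consensus of replicates 1 and 2, without replicate 3, 11 lists instead of 5 passed the permutation test above chance. Among them were mesoderm (permutation, adjusted p = 0.00614), Dpp pathway (0.0146), segment polarity (0.0336), Hox (0.0373), cellularization (0.0198) and proteasome (0.0189). The Dpp pathway list also passed without replicate 1 (0.0225) and without replicate 2 (0.00864), and the segment polarity list without replicate 1 (0.0496). In the 3702 strongest peaks the permutation test passed for the Dpp pathway (14 of 17 genes, adjusted p = 0.00209), Hox (8 of 8, 0.0175) and segment polarity lists (10 of 13, 0.0329). With summits within 1 kb of a start, 12 of 13 segment polarity genes (permutation, adjusted p = 0.000285) and 7 of 9 cellularization genes (0.0286) were bound, and territories of 5 kb held a summit for 9 of 9 cellularization genes (0.0232).

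The dorsal and ventral lists were compared directly, because Zen acts on the dorsal side of the embryo and the mesoderm forms ventrally. The dorsal list exceeded the mesoderm list by 13.3 percentage points, 16 of 16 against 13 of 15 genes, and the difference did not pass Fisher's exact test (two-sided, p = 0.226). In replicates 1, 2 and 3 the difference was 13.3, 7.08 and 13.8 percentage points. It was 20.8, 14.2 and 7.08 without replicate 1, 2 and 3, 27.5 in the 3702 strongest peaks (exact, p = 0.113), 6.67 in the looser set of 14810 peaks and 8.33 with summits within 1 kb of a start, and none of these passed (exact, p of 0.113 to 0.704).

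Among lists of other functions, ribosomal protein genes stood highest, with 76 of 88 bound against 34.4 expected (two-sided permutation test, p = 2e-05, the smallest the random lists can give, adjusted p = 0.000127). *RpL3* (rank 149) was among the genes of this list with the strongest summits, and the libraries gave 72.7 ± 2.08 genes (SD, n = 3). Of the proteasome genes, 27 of 48 were bound against 19.3 (permutation, adjusted p = 0.0622), led by *Rpn5* (rank 201) and *Rpn12R* (rank 213). This list passed without replicate 1 (permutation, adjusted p = 0.0495). Genes of sensory and cuticle families lay below chance. Odorant and gustatory receptor genes had 16 of 119 bound against 50.5 and cuticle protein genes 13 of 96 against 37.3, both with p = 2e-05 by permutation (adjusted p = 0.000127). Their libraries gave 15 receptor genes each and 14.3 ± 4.16 cuticle genes (SD, n = 3). The symbol pattern of the cuticle list also took in *Cpr*, which does not encode a cuticle protein and was among the 13 bound. The strongest receptor genes were *Or85f* (rank 644) and *Gr97a* (rank 957), and the strongest cuticle genes *Cpr76Ba* (rank 791) and *Cpr100A* (rank 1332). The *Gr97a* summit had no counterpart in the lists of replicates 1 and 2.

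The remaining lists did not pass the adjusted permutation test. Muscle structure genes had 5 of 17 bound against 9.71 (permutation, adjusted p = 0.0622), with *Tm1* and *Mlp84B* strongest at ranks 1697 and 1709; against genes with a known symbol the permutation adjusted p was 0.0386. Hemocyte genes had 4 of 12 against 7.08 (permutation, adjusted p = 0.160), among them the GATA factor gene *srp* (rank 757) and *vkg* (rank 3646). Vision genes had 5 of 15 against 7.76 (permutation, adjusted p = 0.258), with *norpA* (rank 516) and *Rh5* (rank 570). Antimicrobial peptide genes had 1 of 14 against 3.68 (permutation, adjusted p = 0.195), the bound gene being *Def* (rank 379); within 1 kb of a start 0 of 14 were bound, below chance (permutation, adjusted p = 0.0381). Heat shock genes had 9 of 15 against 6.90 (permutation, adjusted p = 0.424), where *Hsp23* and *Hsp27* shared a summit at rank 221 and all 6 *Hsp70* genes were unbound. Germ plasm genes had 8 of 12 against 7.05 (permutation, adjusted p = 0.802), with *CycB* (rank 9) and *tud* (rank 1173) strongest. A territory can hold a summit that lies closer to the start of a neighboring gene, as in the case of *Hsp23* and *Hsp27*.

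IDR summits were concentrated at promoters and outside annotated genes and were scarce in coding sequence. The intergenic class took in every base outside a gene, with the upstream side of promoters, so these excesses overlap. An intergenic share away from start sites was not computed. Of the 7405 summits, 46.8% lay within 500 bp of an annotated start site, against 13.6% in circular shifts of the peaks along their arms, a ratio of 3.44. The libraries gave 46.1 ± 0.363% (SD, n = 3). The median distance to the nearest start was 646 bp in the IDR set. Coding sequence held 1.39% of summits against 17.1% in the shifts, and the 3' UTR held 1.40% against 4.89%. The 5' UTR held 8.49% against 3.05%, and other exons 3.28% against 1.78%. Intergenic sequence held 46.6% against 30.7%, and introns 38.8% against 42.5%. Each of these shares had a two-sided permutation p of 0.0002, the smallest the shifts can give, and each library gave the same direction. Across libraries the shares were 1.46 ± 0.336% in coding sequence, 1.45 ± 0.0858% in the 3' UTR, 8.89 ± 1.06% in the 5' UTR and 3.23 ± 0.285% in other exons. Intergenic sequence held 45.6 ± 1.71% and introns 39.4 ± 0.297% (SD, n = 3). The intron deficit did not pass in the looser set of 14810 peaks (log2 ratio −0.044, permutation, adjusted p = 0.142).

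**Figure D3:**
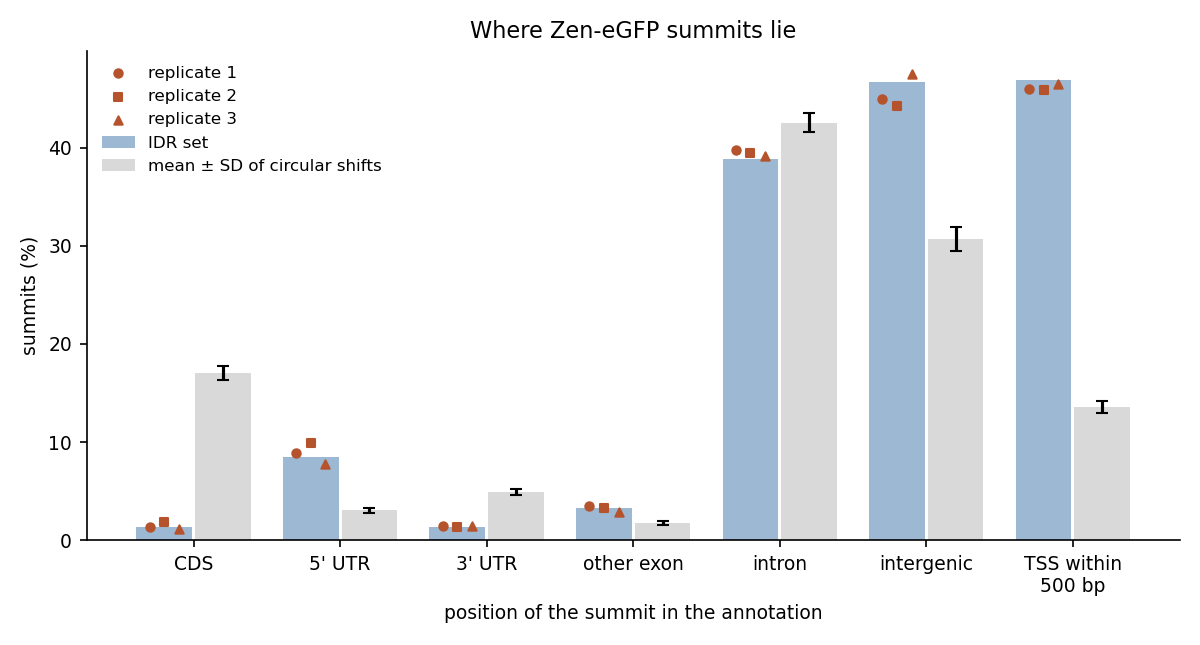
Share of summits (y axis, percent) by position in the annotation (x axis), with the share within 500 bp of a start site at the right. Blue bars are the IDR set, symbols the strongest 7405 summits of each of the 3 replicates, and gray bars the mean of 10000 circular shifts with their SD; 46.8% of IDR summits against 13.6% in the shifts lay within 500 bp of a start site.

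Summits were thinner on the X than on the large autosome arms. The IDR set held 47.2 summits per Mb on X and 43.0 on chromosome 4, against 61.7 on 2L, 53.0 on 2R, 55.5 on 3L and 58.9 on 3R. The ratio of X to the mean of the 4 large autosome arms was 0.825 in the IDR set and 0.813 ± 0.0411 in the libraries (SD, n = 3), below 1 in 3 of 3 libraries. The embryos were of both sexes, and males carry a single X. No test across arms was run. With 3 libraries, an exact test that counts only the libraries with a ratio below 1 cannot reach a p of 0.05.

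Sequence motifs were counted within 100 bp of each summit to ask which factors' sites lie at the summits. The homeodomain core TAATTA was present at 18.6% of IDR summits and at 11.7% of flanking windows 1000 bp away, a log2 ratio of 0.66 (exact binomial test, two-sided, adjusted p = 2.21e-30 over 17 motifs). The libraries gave 0.64 ± 0.03 (SD, n = 3). The Hox-type motif TAATKR was at 52.3% of summits against 39.7% (0.40, exact binomial, adjusted p = 1.45e-51). TAATKR also matches TAATTA, so these motifs are not independent. The summits had a mean GC content of 39.2% against 43.0% in the flanks, and the control TAAATT, the same bases in another order, was also more frequent at summits (33.3% against 23.3%, 0.51). Against random windows matched on GC content the log2 ratio was 0.35 for TAATTA (exact, adjusted p = 2.26e-10) and 0.19 for TAATKR, while the TAAATT difference no longer passed (0.05, exact, adjusted p = 0.252). Against these windows TAATTA was at 0.40, 0.38 and 0.16 in replicates 1, 2 and 3, and TAAATT at 0.09, 0.06 and 0.05. The TAAATT difference passed in replicate 1 (exact, adjusted p = 0.016) and did not pass in replicates 2 and 3 (0.108 and 0.162).

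CAGGTA, the site of the pioneer factor Zelda that opens the early embryonic genome, was at 10.2% of summits against 5.05% of flanks, a log2 ratio of 1.01 (exact binomial, adjusted p = 7.32e-32). The libraries gave 0.90 ± 0.20 (SD, n = 3), with replicate 3 lowest at 0.67. The CAGGTA control CGAGTA did not pass (−0.06, exact, adjusted p = 0.586), but was lower with the strongest summit of each interval, a setting chosen after the data were seen (−0.23, exact, adjusted p = 0.0402), and in replicate 3 (−0.27, exact, adjusted p = 0.0184). Sites of a pair of promoter and insulator proteins were also frequent. GGTCACACT, the M1BP site, was at 2.90% of summits against 0.216% (3.71, exact, adjusted p = 2.53e-45), and CGATA, the BEAF-32 core, at 31.2% against 21.2% (0.55, exact, adjusted p = 1.51e-41). The T-box motif GGTGTGA had a log2 ratio of 0.50 (exact, adjusted p = 0.00685), which did not pass without replicate 1 (0.50, exact, adjusted p = 0.0552), in the 3702 strongest peaks (0.21, 0.526) or within 50 bp (0.16, 0.673). It was highest without replicate 2 (0.94, exact, adjusted p = 2.6e-05) among the sets without a replicate, and it passed in the looser set of 14810 peaks (0.53, exact, adjusted p = 4.84e-05) and against GC-matched windows (0.98, exact, adjusted p = 5.46e-07).

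The difference of GAGAG, the site of GAGA factor, from the flanks did not pass (23.8% against 22.8%, 0.06, exact binomial, adjusted p = 0.215). It passed without replicate 3 (0.13, exact, adjusted p = 0.0174), in the looser set of 14810 peaks (0.088, exact, adjusted p = 0.0058), against flanks 3000 bp away (0.15, exact, adjusted p = 0.0008) and against GC-matched windows (0.25, exact, adjusted p = 4.49e-08). In the libraries it passed in replicates 1 and 2 (0.16 in both, exact, adjusted p = 0.000411 and 0.0003). The direction was the opposite in replicate 3 (−0.06, exact, adjusted p = 0.209) and within 50 bp of the IDR summits (−0.12, 0.118), without passing. The GATA motif WGATAR (0.12, exact, adjusted p = 0.00143) and the Caudal motif TTTATG (0.15, exact, adjusted p = 0.00182) were more frequent at summits, and neither passed against GC-matched windows (0.02 and 0.03, exact, adjusted p = 0.722 and 0.658). WGATAR did not pass in the 3702 strongest peaks either (0.08, exact, adjusted p = 0.136). The Mad motif GNCGNC was less frequent at summits than in flanks (−0.31, exact, adjusted p = 2.42e-20) and did not pass against GC-matched windows (0.05, exact, adjusted p = 0.21), though it was higher than these in replicate 2 (0.10, 0.00431). The Brinker motif TGGCGY did not pass against the flanks (−0.08, exact, adjusted p = 0.229). It was lower than in flanks in the 3702 strongest peaks (−0.23, exact, adjusted p = 0.0138), in the looser set (−0.11, 0.0106) and with flanks at 3000 bp (−0.14, 0.0176), and higher than in GC-matched windows (0.26, exact, adjusted p = 5.06e-05). The Twist motif CACATG was lower than in flanks (−0.22, exact, adjusted p = 0.0061) but did not pass against GC-matched windows (−0.02, exact, adjusted p = 0.898), without any one replicate (−0.12 to −0.19), in the 3702 strongest peaks (−0.11, 0.448), in the looser set (−0.026, 0.669) or with flanks at 3000 bp (−0.14, 0.0945). Among the libraries it passed in replicate 3 alone (−0.18, exact, adjusted p = 0.0378).

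The Bicoid motif TAATCC (0.09, exact, adjusted p = 0.356), the Dorsal motif GGGWWWWCC (0.38, exact, adjusted p = 0.0563) and the composite Exd and Hox motif TGATNNAT (−0.05, exact, adjusted p = 0.487) did not pass; TGATNNAT was lower against GC-matched windows (−0.25, exact, adjusted p = 7.73e-05) and in the looser set (−0.10, 0.0274). GGGWWWWCC was at 0.12 without replicate 1, 0.03 with flanks at 3000 bp and 0 in the looser set. It passed in replicate 1 against flanks (0.45, exact, adjusted p = 0.0213), and in replicates 1 and 3 against GC-matched windows (0.55 and 0.54, exact, adjusted p = 0.00653 and 0.00924). TAATCC turned negative without replicate 1, 2 or 3 (−0.03, −0.09 and −0.11), in the 3702 strongest peaks (−0.09) and in the looser set (−0.04), and did not pass in any of them (exact, adjusted p of 0.366 to 0.844).

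**Figure D4:**
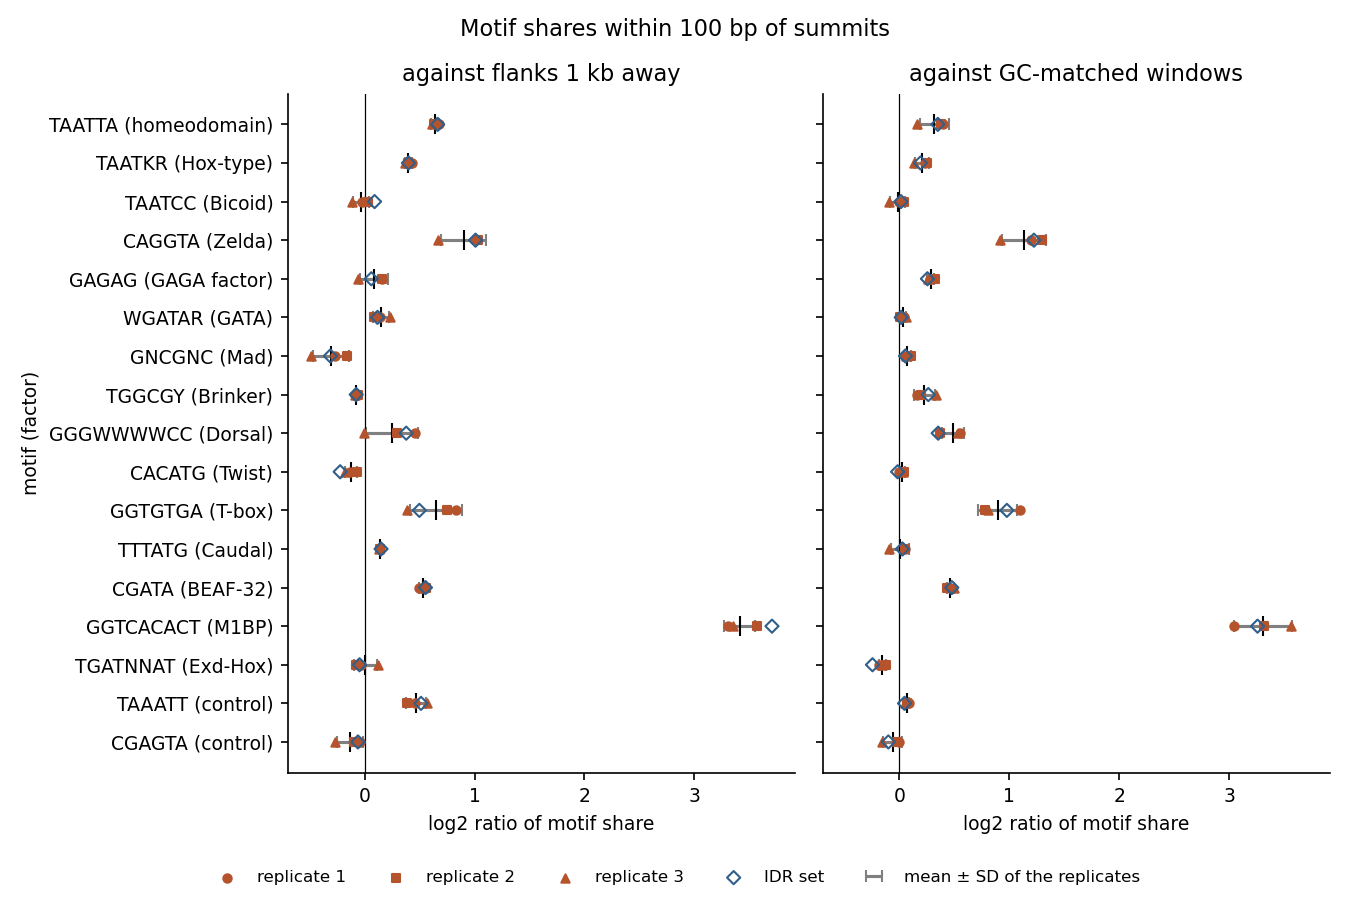
log2 ratio of the share of summits with a motif to the share of control windows (x axis) for 17 motifs (y axis), against flanks 1000 bp away on the left and random windows matched on GC content on the right. Filled symbols are the 3 replicates, black ticks and bars their mean and SD, and open diamonds the IDR set; TAATTA is at 0.66 on the left and 0.35 on the right, CAGGTA at 1.01 on the left and 1.22 on the right.

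Strong peaks carried TAATTA more often than weak ones. Among the 1481 IDR summits of highest signal 22.4% had TAATTA, against 14.9% of the 1481 of lowest signal (Fisher's exact test, two-sided, adjusted p = 5.96e-07 over 3 motifs). CAGGTA was at 12.6% against 9.05% (exact, adjusted p = 0.00311) and GAGAG at 24.7% against 24.4% (exact, adjusted p = 0.864). Within 50 bp of the summit the CAGGTA difference was 1.62 percentage points and did not pass (exact, adjusted p = 0.0781). The strongest summits had a mean GC content of 37.9% and the weakest 40.3%, and the control TAAATT, compared after the data were seen, also differed (36.9% against 30.2%, exact, adjusted p = 0.000373 over 14 motifs). Within GC bins, chosen after the data were seen, the difference was 5.64 percentage points for TAATTA and 5.53 for CAGGTA (permutation p = 0.0002 for both, the smallest the permutations can give), and that of TAAATT did not pass (1.21, permutation p = 0.475).

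The replicates shared most of their strong peaks. Of each library's strongest 7405 summits, 71.6% of replicates 1 and 2, 69.0% of replicates 1 and 3 and 64.6% of replicates 2 and 3 lay within 100 bp of each other, a mean of 68.4 ± 3.56% (SD over 3 pairs). Circular shifts gave at most 1.77%. In replicates 1, 2 and 3, 56.5%, 55.8% and 56.6% of these summits were found among the strongest 7405 of both other libraries, and 15.9%, 19.6% and 23.1% in neither. Against the full lists of 30000 summits, 3.27%, 5.08% and 4.54% were in neither other library. Of the IDR summits, 84.8%, 78.8% and 79.8% were among the strongest 7405 of replicates 1, 2 and 3 (81.1 ± 3.20%, SD, n = 3), and 4272 (57.7%) were in all 3. Across IDR peaks matched in a pair of libraries, the signal values had a Spearman rho of 0.767 for replicates 1 and 2 (6872 peaks), 0.613 for 1 and 3 (6823 peaks) and 0.57 for 2 and 3 (6727 peaks); peaks are not independent replicates. The peak calls of all 3 libraries used the same control alignments, which can add shared peaks.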

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

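The settings using the strongest summit of each interval, local shifts and GC bins for motifs by signal were chosen after the data were seen. For the main results, 135 values under other settings kept their side of the threshold or moved by less than the spread between replicates. A further 17 moved farther, 5 newly passed and 2 no longer passed. A change of direction was counted as kept where neither the main nor the other value passed. The share of summits near a start, the summit enrichment of TAATTA, TAATKR and CAGGTA and the dorsal list kept direction and side under each alternative run. For single lists and motifs, 229 values were counted as kept, 25 no longer passed and 23 newly passed. Another 2 reversed direction where the main or the other value passed. The mean overlap of replicates (68.4%) became 76.6% for any 1 bp of overlap, 58.7% for 50% of both peaks, 54.0% and 76.1% for summits within 50 and 250 bp, 50.9% for all 30000 peaks, and 64.6 to 71.6% without a replicate. The share of IDR peaks found (81.1%) became 85.6%, 70.1%, 71.8%, 85.5% and 95.8% under the same settings, which follows from the looser or stricter match. In the looser set, introns were at a log2 ratio of −0.044 and 3 lists instead of 5 passed above chance. A known-symbol background also gave 3 lists, and leaving out a replicate gave 4 to 11. The X ratio was 0.722 in the strongest 3702 peaks. Without a replicate, the mesoderm list ranged from a log2 ratio of 0.50 to 0.87 and GAGAG from 0.0024 to 0.13. GAGAG was at 0.088 in the looser set, 0.15 with flanks at 3000 bp and 0.25 with GC-matched windows. CAGGTA by signal was 1.62 percentage points within 50 bp. The *zen* window was at the 96.6th percentile for 50 kb and the 99.3rd for 20 kb. Against GC-matched windows, GNCGNC turned to 0.055 and TGGCGY to 0.26. Apart from the match settings, the cause was not tested. Read depth is unknown, so its limit on each library's list cannot be given.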

Other observations

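The comparisons of broad intervals, of motifs by signal beyond TAATTA, CAGGTA and GAGAG, of signal with width among wide intervals and of the *zen* window with windows of similar summit number were chosen only after the result was seen, as were the GC and TAATTA tests of replicate 3. The windows matched on GC content were set beforehand, and their use with the TAAATT control against A/T-rich sequence was chosen after the values were seen. The 600 bp limit followed an unplanned look at widths, ranks and motifs, and broad peaks were counted per summit before they were counted per interval.

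Broad intervals gathered at genes of the dorsal list. Of the 7243 IDR intervals, 147 were wider than 600 bp, and 123 of the 6532 protein-coding genes bound by the strongest summit of an interval (1.88%) had one in their territory. In the dorsal list, 8 of 16 genes had one (*Doc2*, *Doc3*, *cv-2*, *dpp*, *egr*, *pnr*, *ush* and *zen*), in 10 distinct intervals, against 0.447 in random lists of bound genes matched on territory length (permutation p = 2e-05, the smallest they can give, adjusted p = 0.00038 over 19 lists). The random lists were not matched on the number or strength of summits, and the dorsal list held 69 summits with a median strongest rank of 423.5. The excess was therefore not separated from more or stronger summits at these genes. No other list passed: the pair-rule list had 2 genes and the Dpp pathway list 3 (permutation, adjusted p = 0.123 for both). Replicates 1, 2 and 3 had 137, 92 and 15 such intervals among their strongest 7405 summits, and 8, 7 and 2 dorsal genes with one. An intron of *ush* held one of the widest, on 2L from 518014 to 519766 (1753 bp, rank 60), and the *egr* interval spanned 1705 bp. CAGGTA lay at the strongest summit of 30.6% of broad intervals against 9.47% of the others (Fisher's exact test, two-sided, adjusted p = 4.39e-12), and 25 of 147 broad against 3407 of 7096 other intervals had that summit within 500 bp of a start site (exact, adjusted p = 5.08e-14). CGATA was less frequent at broad intervals (20.4% against 31.8%, exact, adjusted p = 0.00595). The TAATTA difference did not pass (21.1% against 18.6%, exact, adjusted p = 0.453). GAGAG (29.9% against 23.6%, exact, adjusted p = 0.117) and GGTCACACT (0.680% against 3.02%, 0.161) did not pass either.

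Sites of promoter proteins were least frequent in the strongest peaks, without a steady rise toward the weakest. Across 5 groups of 1481 IDR summits, from strongest to weakest, GGTCACACT was at 0.675, 2.63, 3.78, 3.98 and 3.44%. CGATA was at 24.9, 31.1, 33.1, 35.3 and 31.5% in the same groups. The M1BP site GGTCACACT was at 0.675% of the 1481 strongest IDR summits and at 3.44% of the 1481 weakest (Fisher's exact test, two-sided, adjusted p = 5.06e-07 over 14 motifs), and CGATA of BEAF-32 at 24.9% and 31.5% (exact, adjusted p = 0.000305). TAATKR, which also matches TAATTA, went the other way, with 59.1% and 46.6% (exact, adjusted p = 1.67e-10). The strongest summits were lower in GC content, and TAAATT rose with signal too (36.9% against 30.2%), while GNCGNC (28.5% against 35.8%, exact, adjusted p = 0.000118) and TGGCGY (11.1% against 15.9%, 0.000373) fell. Within GC bins the strongest minus the weakest summits gave −2.73 percentage points for GGTCACACT and 11.7 for TAATKR (permutation p = 0.0002 for both, the smallest they can give), −6.01 for CGATA (permutation p = 0.0006) and −2.94 for TGGCGY (permutation p = 0.0232). TAAATT (1.21, permutation p = 0.475) and GNCGNC (−2.42, permutation p = 0.138) did not pass there; these p values are not adjusted.

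The strongest IDR peak lies 8967 bp upstream of *zen*, the tagged gene; no biological explanation was tested, since the design has a single group. Width alone did not order the widest peaks: the other 19 intervals of at least 1000 bp had a median signal of 1568 against 7785, and the 7 intervals wider than this one ranked from 7 to 661. Whether a signal value that grows with peak width adds to it cannot be told apart from a stronger site, since this peak was picked as the highest and the Spearman rho of width and signal among those 19 was 0.00877 with a wide 95% bootstrap interval (−0.529 to 0.487). Extra copies of the *zen* region carried by the transgene may add to it: 12 pooled-list peaks outside the IDR set lay in the 20 kb around *zen*, the 96.6th percentile of 6689 other windows. Among the 150 windows with a similar number of IDR summits the same number was only at the 75th percentile, so extra copies and dense binding cannot be told apart without read coverage, which was not analysed here.

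Replicate 3 ranked summits with CAGGTA lower than the other replicates did, by a difference of −16.0 percentile points between summits with and without it over 6542 peaks found in all 3 libraries. GC content bias was argued against as the whole cause, since −10.1 remained within GC bins (95% bootstrap interval −12.0 to −8.27), though the smaller value leaves room for a part. Within classes of the width of the IDR intervals, −14.3 remained (−16.3 to −12.4). The widths called in replicate 3 itself were not used, so this value does not decide whether narrower calls there contribute. Whether a smaller share of Zen-bound fragments in replicate 3 contributes was not decided. Within GC bins summits with TAATTA also ranked lower, by −4.75 (−6.13 to −3.46), but without bins the difference was −0.922 (−2.41 to 0.503). TAATTA does not mark Zen-bound fragments alone. Summits in intervals wider than 600 bp also ranked lower, by −19.0 (−10.5 within GC bins), and those with the M1BP site higher, by 5.19. These intervals resample peaks and do not measure variation between libraries. No biological explanation was tested, and a difference in embryo age within the 0 to 4 h collection stays open.

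TAATTA was more frequent at summits than in flanks. Low GC content was argued against as the whole cause, since against windows matched on it the log2 ratio was 0.35 (exact, adjusted p = 2.26e-10), while the control TAAATT was at 0.05. In replicate 1 the control passed too, at 0.09 against 0.40 for TAATTA. TAATTA reads the same on both strands and TAAATT does not, so the control is more frequent and its ratio not fully comparable. Coding sequence, with 1.39% of summits against 17.1% in shifts, was not matched, so noncoding composition can add to the excess. Open promoter chromatin recovered regardless of the tagged protein and Zen binding cannot be told apart: within bins of GC content and start-site distance the strongest summits had TAATTA 5.53 percentage points more often than the weakest (permutation p = 0.0004). The bound set beforehand on this value was wrong, since CAGGTA, the site of another factor, rose by 5.26 in the same bins, so that such a rise does not need the tagged protein. Sites of other homeodomain proteins share this core and were not told apart, and no biological explanation was tested, since no library without the tagged protein was analysed here.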
